A study of Mus musculus with 6 samples.

How the data were processed

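RNA from bone marrow-derived macrophages of 2 genotypes (wild type and Irak2 knockout), untreated or stimulated for 2 h with 1 µg/ml R848 or 1 µg/ml CpG B, was measured on 6 Illumina mouseRef-8 v2 bead arrays, 1 per group. Per the labels' protocols, total RNA was extracted with TRIZOL and amplified by a single round of in vitro transcription into biotin-labelled cRNA. The groups were taken from the genotype and agent given in the labels. The labels carry no replicate numbers.

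The authors deposited a table of probe intensity values that were not normalized between arrays, made with BeadStudio per the submitters' processing notes, with the version not given in the sources used here. Between 33.4% and 34.4% of the intensities on an array were below 0, so background had been subtracted, which is read from the values. Beside each intensity the deposited table gives a detection p-value, per the file headers, whose steps correspond to about 800 negative-control bead types. Array medians ranged from 20.6 to 27.7 intensity units and the highest intensity was 45638. The lowest intensity of a detected probe was 68.2 to 96.6, depending on the array.

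The authors also deposited a processed intensity per probe and sample, whose scale was worked out by setting it against the scanner values. These values are linear, not centred, and quantile normalized, and their column medians were 24.2 to 24.4. For the 4 stimulated samples, 99.7% to 99.8% of the values lay within 0.5 units of the quantile-normalized array. For the untreated samples this held for 6.09% (wild type) and 6.27% (knockout), so these columns were taken to be means of more than 1 array. If a column is a mean of 2, the values of the other array follow, and once sorted 99.7% of them lay within 0.5 units of the common quantile distribution in each genotype, against 66.7% and 67.2% if it is a mean of 3. The second untreated array of each genotype was therefore recovered as the column times 2 minus the deposited array. Whether these arrays came from other cultures or from the same RNA is not given in the sources used here, so the spread between them, and any p-value that rests on it, may be technical.

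Probes were named through the platform annotation, which gives 1 gene for 23978 of the 25697 probes and several genes for 0, and 1719 probes were unnamed here and not used. Symbols were compared with a RefSeq gene table of assembly GRCm38.p6 through gene identifiers, which 16 probes lacked in that table. This table served only for names, chromosomes and the order of neighbouring genes, because no genome build is named for the array values. The probes gave 16593 genes, of which 2751 had several probes, and a gene was represented by the probe with the highest mean log2 value.

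Values were computed in R 4.3.3 with limma 3.58.1. The function neqc inferred the background from the detection p-values (normexp), added an offset of 16, applied quantile normalization over the 6 arrays and took log2. A comparison used genes detected (p under 0.01) on at least 1 of its arrays, and the limma fits used the 7149 genes detected on at least 1 of the 6. Single-array differences were counted at an absolute log2 difference of at least 1 and have no p-value. Differences of responses between genotypes used 4 arrays. The 4 planned limma fits, with empirical Bayes moderation and Benjamini-Hochberg adjustment, used the 6 arrays: the R848, CpG B and genotype effects came from an additive model with 2 residual degrees of freedom, in which any interaction adds to the spread, and an interaction shared by both stimuli left 1 degree of freedom. Comparisons that use the same untreated array share its chance values. The R848 minus CpG B differences of wild type and knockout share no array.

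After the data had been seen, a limma fit of the 6 group means on 8 arrays was added, with the recovered untreated arrays, from the processed values with the same offset. Its 2 residual degrees of freedom come from the untreated pairs alone, so the stimulated arrays are assumed to vary like them. Genes at the floor on the untreated arrays have no measured spread there, and the fit was therefore repeated on the 6366 genes detected on both deposited untreated arrays.

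Before the data were examined, 17 gene lists and 8 sets of cell-type markers were fixed, and so were the designs, the alternatives and the rule for naming genes. That rule takes up to 10 genes in each direction per comparison with the largest log2 difference of the same sign in the processed values, up to 4 members per list in each direction, and the 10 genes with the smallest adjusted p in each direction of each fit. Any list member may be named. Genes of the 8-array fit, and Tlr7 and other members given as contrasts, were chosen after their values were seen. List medians were set against 10000 random lists matched on mean expression in 20 bins.

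The alternatives were no background correction, the processed values, median scaling in place of quantile normalization, an offset of 50, other detection filters (p under 0.05 on 1 array, under 0.01 on all 6, or none), the mean of a gene's probes, a size of 1.5, an intensity trend with a robust prior, and models without the genotype term, the agent term or each agent's arrays. The deposited values were read and annotated with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, the tests of chromosomes used R, and plots matplotlib 3.10.9.

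The tests were tried on simulated arrays of the 7149 genes with 200 genes changed by a known amount and noise taken from the untreated pairs. The simulated noise had the same SD for every gene, with no floor and no interaction. Real genes differ in spread, so recovery in the data may be lower than the shares given here. At a log2 change of 1 the additive fits recovered 99% (R848), 98% (CpG B) and 100% (genotype) of changed genes, and at 2 all of them, with 4, 19 and 12 false calls. The shared interaction recovered 50% at 1 and 100% at 2, with 7 false calls. In the 8-array fit, 83% and 100% were recovered for the R848 response of wild type (11 false calls), 43% and 100% for the difference of R848 responses (1 false call), and 21% and 99% for the genotype difference after R848 minus that after CpG B (4 false calls).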

Results

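Gene expression was measured in macrophages grown from the bone marrow of female mice, either wild type or deficient in Irak2, with the strain given as 129/BL6. The cells had been cultured for 5 days in medium conditioned by L929 cells, which supplies the macrophage growth factor M-CSF. They were then left untreated or exposed for 2 h to 1 µg/ml R848 or 1 µg/ml CpG B. R848 (resiquimod) is a small imidazoquinoline that activates Toll-like receptor 7 in the mouse, and B-class CpG oligonucleotides activate Toll-like receptor 9. Both endosomal receptors signal through the adaptor MyD88 and the IRAK kinases, of which IRAK2 is one member, so the design asks how far each response differs when IRAK2 is missing. Each of the 6 groups was hybridised to 1 Illumina mouseRef-8 v2 bead array of 25697 probes. Between 8968 and 9718 probes (34.9% to 37.8%) were detected per array at a detection p-value under 0.01, and 7149 of 16593 named genes were detected on at least 1 array.

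No group had a replicate, so a difference between single arrays carries no p-value, and genes were counted at a log2 difference of at least 1 (2-fold). For scale, the submitters' normalized values of the untreated columns were taken to be the means of 2 arrays, which gave a second untreated array per genotype. Over the 7149 genes, 36 (0.504%) differed by 2-fold or more between the untreated wild-type arrays, and 21 (0.294%) between the untreated knockout arrays. The number of arrays limits the precision of every value. A gene below background on the dimmer of both arrays has only a bound, and its fold is then given as at least the bright array's normalized value over the higher of the lowest detected signal and the gene's own value on the dim array. Genes are said to have risen or fallen only where limma called them at an adjusted p-value under 0.05.

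Irak2 transcript was detected on every array, including those of the knockout. In wild-type cells the intensity of 1 of its 2 probes was 534 untreated, 3695 after R848 and 2618 after CpG B. The knockout arrays gave 378, 835 and 622 in the same order. The other probe read 342, 2594 and 2117 in wild type and 339, 641 and 556 in the knockout. These intensities were not normalized between arrays. After normalization the 2 probes gave a 7.02-fold and 7.77-fold higher value after R848 in wild type, against 2.67-fold and 2.28-fold in the knockout. Untreated, the log2 difference of knockout from wild type was -0.57 and -0.11, and after R848 it was -1.97 and -1.88. Which part of the gene was deleted is not given in the sources used here, and a probe outside that part does not check the genotype labels.

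R848 acted strongly on wild-type macrophages within 2 h. The largest differences were in mediators of acute inflammation. Interleukin-1 beta (Il1b) was at least 269-fold higher, the acute-phase protein gene Saa3 at least 331-fold and the cytokine signalling inhibitor Socs3 at least 271-fold. The neutrophil chemoattractants Cxcl2 and Cxcl1 were 166-fold and 163-fold higher, the T-cell chemoattractant Ccl5 110-fold and Tnf 64.5-fold. Endothelin-1 (Edn1) was at least 58.5-fold higher, Il6 at least 28.3-fold and the membrane metalloproteinase Mmp14 at least 25.5-fold. The genes that were lowest relative to untreated cells included the oxysterol receptor Gpr183 (at least 10.7-fold lower), the glycosyltransferase Gcnt1 (17.3-fold), Lbh (17.1-fold), the lysoplasmalogenase Tmem86a (at least 10.2-fold), the lysophosphatidic acid receptor Lpar6 (14.9-fold), the urokinase gene Plau (12.8-fold) and the cell-cycle factor E2f2 (12.4-fold). In total 1062 of 6819 genes passed the 2-fold size, 525 of them higher and 537 lower. The median log2 difference of the tested genes was -0.10 with quantile normalization and 0.003 with median scaling.

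Most members of the fixed lists of inflammatory mediators were higher after R848 in wild type. Of 14 detected inflammatory cytokines 13 were higher by 2-fold or more and none lower, with a median log2 difference of 3.46, and of 14 chemokines 13 were higher, with a median of 2.43. Of 23 negative feedback regulators 18 were higher, among them the inhibitor of NF-kB Nfkbia (log2 difference 3.76), the ubiquitin-editing enzyme Tnfaip3 (5.38) and the ribonuclease Zc3h12a (4.43), and 1, the G-protein regulator Rgs1, was lower (-2.21). All 12 secondary response genes were higher, and so were 13 of 15 effector enzymes, including the prostaglandin synthase Ptgs2 (at least 20.2-fold) and inducible nitric oxide synthase Nos2 (at least 9.13-fold), while Plau and arginase Arg1 (-1.34) were lower. Of 25 interferon-related genes 20 were higher, led by the guanylate-binding proteins Gbp3 (5.08) and Gbp2 (4.33) and by Mx1 (at least 5.50-fold). Of 16 costimulatory and adhesion molecules 12 were higher, such as Cd40 (4.02), Cd69 (4.92) and Icam1 (3.86). The 19 cell-cycle genes went the other way, with 10 lower and none higher, among them the replication helicase subunit Mcm2 (-1.53) and the ribonucleotide reductase subunit Rrm2 (-1.43). None of the 10 reference genes passed the size, and their median log2 difference was -0.17.

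**Figure D1:**
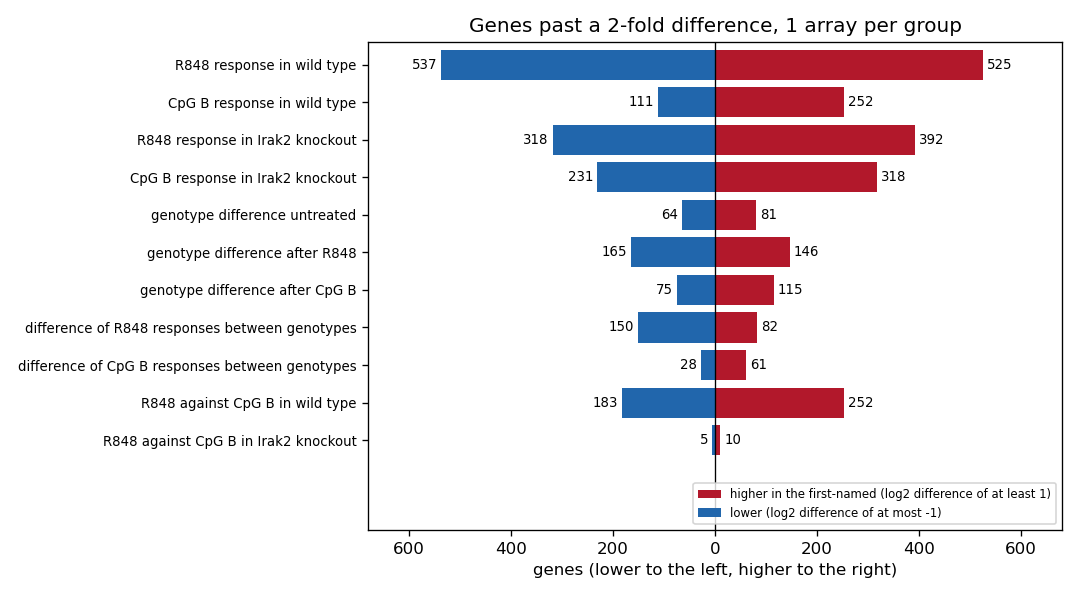
Bars give the number of genes with a log2 difference of at least 1 (right) or at most -1 (left) in each single-array comparison, on an axis of gene counts. R848 in wild type gave the longest bars (525 and 537 genes), and R848 against CpG B in the knockout the shortest (10 and 5).

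CpG B gave a smaller response in wild-type cells, led by many of the genes that led the R848 response. Il1b was at least 52.1-fold higher, Saa3 at least 75.9-fold, Socs3 at least 65.1-fold, Cxcl1 81.8-fold, Cxcl2 52.6-fold and Tnf 41.4-fold. The nicotinic acid receptor Hcar2 was at least 26.1-fold higher, Ccl5 26.8-fold and the fatty acid receptor Gpr84 19.7-fold. The lower genes included the organic anion transporter Slco2b1 (5.51-fold), Dmwd (5.08-fold), the immediate early factor Egr1 (4.85-fold), the prostaglandin dehydrogenase Hpgd (4.09-fold) and the replication licensing factor Cdc6 (4.02-fold). For Egr1 the log2 difference was -2.28 here and -1.41 in the submitters' processed values, whose untreated column was taken as a mean of 2 arrays. The count was 363 of 6925 genes, 252 higher and 111 lower. Of the 14 cytokines 8 were higher, of the 14 chemokines 7, of the 23 feedback regulators 16 and of the 12 secondary response genes 10. Interferon-related genes responded in smaller number, with 8 of 25 higher, among them Gbp3 (3.14), Gbp2 (2.52) and the antiviral gene Rsad2 (1.76). The effector enzymes had 10 higher and 2 lower, the costimulatory and adhesion molecules 12 higher, and the cell-cycle genes 2 lower.

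In the knockout, inflammatory mediators again had the largest differences after R848. Il1b was at least 95.7-fold higher, Saa3 174-fold, Socs3 82.7-fold, Cxcl1 at least 145-fold, Cxcl2 at least 101-fold and Ccl5 47.9-fold. The cystine transporter Slc7a11 was at least 24.0-fold higher, Mmp14 at least 28.7-fold and the serpin Serpinb2 at least 9.48-fold. Rasgrp3 was 13.3-fold lower, Slco2b1 at least 9.39-fold, Plau 8.70-fold, the uracil glycosylase Ung at least 9.18-fold and thrombomodulin (Thbd) at least 5.63-fold. The count was 710 of 6796 genes, 392 higher and 318 lower. Of the lists, 11 of 14 cytokines, 11 of 14 chemokines, 18 of 23 feedback regulators, 17 of 25 interferon-related genes and all 12 secondary response genes were higher, and 9 of 19 cell-cycle genes were lower.

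CpG B in the knockout gave 549 of 6860 genes, 318 higher and 231 lower. Il1b was at least 87.5-fold higher, Saa3 105-fold, Cxcl1 at least 78.6-fold, Cxcl2 at least 51.0-fold, Ccl5 60.5-fold and Socs3 60.3-fold. Cxcl10, an interferon-inducible chemokine, was at least 19.0-fold higher, Slc7a11 at least 16.2-fold and Mmp14 at least 15.9-fold. Slco2b1 was at least 10.4-fold lower, Ung 6.67-fold, Gpr183 6.64-fold and Rasgrp3 6.49-fold. Here 10 of 14 cytokines, 9 of 14 chemokines, 17 of 23 feedback regulators, 15 of 25 interferon-related genes and 11 of 12 secondary response genes were higher, and 6 of 19 cell-cycle genes were lower.

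Averaged over both genotypes in an additive limma model (2 arrays per agent), R848 changed 2103 of 7149 genes, of which 866 rose and 1237 fell. Cxcl1 rose by 7.40 on the log2 scale (SE 0.123, adjusted p = 2.85e-05) and Cxcl2 by 7.39 (SE 0.203, adjusted p = 0.000235). Gpr84 (4.33), the apoptosis receptor Fas (4.28), Tlr2 (3.15), the B-cell transcription factor Pou2f2 (3.09) and the endocytic protein gene Ehd1 (2.60) rose at an adjusted p of 0.000938. The transcription factor Etv5 (-2.15), the inhibitory SMAD gene Smad6 (-1.90), the receptor Notch4 (-1.86), Dmwd (-2.72) and Rasgrp3 (-3.67) fell at an adjusted p of 0.00172. CpG B changed 621 genes, with 336 rising and 285 falling. Cxcl1 rose by 6.46 (adjusted p = 6.13e-05), Cxcl2 by 6.07 (0.000709), Pou2f2 by 3.26 (0.00108) and Gpr84 by 4.17 (0.00133), while Notch4 (-1.83, adjusted p = 0.00366), the replication factors Dscc1 (-1.67, 0.00579) and Timeless (-1.56, 0.00582) and Zfp36l1 (-1.33, 0.0067) fell. Without the genotype term the same model called 1280 and 259 genes.

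By list, limma's R848 effect called 10 of 14 cytokines as risen (13 adjusted over the list alone), 12 of 14 chemokines (14 adjusted over the list alone), 18 of 23 feedback regulators with 2 fallen (20 and 2 adjusted over the list alone), and 20 of 25 interferon-related genes (22 adjusted over the list alone). All 12 secondary response genes rose, also adjusted over the list alone, as did 12 of 15 effector enzymes (13 adjusted over the list alone; 2 fell either way) and 13 of 16 costimulatory and adhesion molecules (14 adjusted over the list alone). In the list of transcripts with AU-rich elements, which shares most members with those lists, 13 of 16 rose and 2, Fos (-1.94 in wild type) and Plau, fell, with the same counts adjusted over the list alone. The cell-cycle list had 15 of 19 genes fallen (16 adjusted over the list alone). Among 28 genes of Toll-like receptor and IRAK signalling 13 rose and 1 fell (14 and 3 adjusted over the list alone), including the adaptor Traf1 (4.82 in wild type, 4.46 in the knockout), Tlr1 (2.47 and 2.39) and the kinase Ikbke (2.87 and 2.63), whereas Tlr7, the receptor for R848, had log2 differences of 0.20 and 0.01. Cholesterol synthesis genes had 8 of 15 risen (10 adjusted over the list alone), for example the sterol demethylase Cyp51 (1.38 and 1.42) and Mvd (1.17 and 1.33).

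The CpG B effect called 5 of 14 cytokines (9 adjusted over the list alone), 8 chemokines (11), 11 feedback regulators with 1 fallen (17 and 2), 6 interferon-related genes (12), 8 secondary response genes (11), 9 effector enzymes with 2 fallen (12 and 2), 12 costimulatory and adhesion molecules (13) and 8 fallen cell-cycle genes (14), where the values in brackets were adjusted over the list alone. Signalling genes had 8 risen (10 with 1 fallen adjusted over the list alone), cholesterol genes 5 (6) and transcripts with AU-rich elements 11 with 1 fallen (13 and 2). The NF-kB subunits and IRF factors had 6 of 11 risen and 3 fallen with R848, unchanged in number over the list alone, and 4 risen with CpG B (6 adjusted over the list alone), with Nfkb2 (3.33 after R848 and 2.54 after CpG B in wild type) and Relb (at least 9.54-fold and 6.27-fold) leading. The 10 immediate early factors split, with 5 risen (Junb 2.44 and Ier3 2.38 in wild type) and 4 fallen (Egr1 -1.40 and Klf2 -2.44) after R848, the same adjusted over the list alone, and 3 risen with 2 fallen after CpG B (4 and 3 adjusted over the list alone). The wild-type Egr1 value uses the same untreated array as its CpG B difference, which was smaller in the submitters' processed values.

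Of 15 macrophage identity genes 4 rose and 3 fell with R848, and 3 rose and 1 fell with CpG B (4 and 3, and 4 and 2, adjusted over the list alone). The endotoxin co-receptor Cd14 was higher by 1.48 after R848 and by 1.22 after CpG B in wild type, and Trem2 had a log2 difference of -1.02 after R848. Among 13 heat shock and stress genes 4 rose and 2 fell with R848 and 3 rose and 2 fell with CpG B (6 and 2, and 5 and 2, adjusted over the list alone), with Slc7a11 the largest. Of 16 glycolysis and hypoxia genes 4 rose with R848 (4 adjusted over the list alone), among them the hexokinase Hk2 (0.67 in wild type) and the oxygen-sensing factor Hif1a (1.42). For CpG B limma called 0 of these 16 genes, and for either stimulus 0 of the 10 reference genes, both over all genes and adjusted over the list alone. Over all 7149 genes 3040 had an unadjusted p under 0.05 for R848 and 1979 for CpG B.

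A set of 63 genes differed between the genotypes by 2-fold or more in each of the 3 conditions, 43 higher and 20 lower in the knockout. Another detected probe was available for 10 of them. Ctse, Pclaf, Haus1, Lars2, Usp25, Plk1 and Uchl1, given below, had none. Untreated, 145 of 6724 genes differed by 2-fold or more, 81 higher and 64 lower in the knockout. The aspartic protease cathepsin E (Ctse) was at least 4.98-fold higher in the knockout untreated, at least 3.81-fold after R848 and at least 5.67-fold after CpG B. The PCNA-binding factor Pclaf was 12.4-fold, 8.92-fold and 8.31-fold higher, the mitotic spindle gene Haus1 at least 9.30-fold, 6.81-fold and 8.70-fold, and the mitochondrial leucyl-tRNA synthetase Lars2 at least 6.12-fold, 4.96-fold and 6.76-fold. The interferon-inducible membrane gene Ifitm1 was at least 9.49-fold and the proteasome subunit Psmd8 11.9-fold higher untreated. Among genes lower in the knockout, the ubiquitin protease Usp25 was at least 7.51-fold, 13.8-fold and 11.4-fold lower, the mitotic kinase Plk1 16.7-fold, 9.08-fold and 12.3-fold, and the ubiquitin hydrolase Uchl1 at least 2.30-fold, 2.67-fold and 2.59-fold. In limma's genotype effect averaged over agents (3 arrays per genotype) 243 of 7149 genes changed, 126 higher and 117 lower in the knockout, with an adjusted p of 0.00046 for Ctse and Haus1, 0.000533 for Usp25, 0.000793 for Lars2, 0.00084 for Pclaf, 0.000935 for Uchl1 and 0.000991 for Plk1. The number depended on the arrays used: 9 genes without both untreated arrays and 90 without both CpG B arrays. Whether the 3 arrays of a genotype came from separate mice or cultures is not given in the sources used here. The spread behind these p-values is that of the genotype difference over the 3 conditions, so it may leave out variation between mice or cultures. This limit holds for every p-value of the genotype effect, here and below.

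Cell-type markers differed between the arrays of the genotypes as well, with the same limit on their p-values. Of 5 detected dendritic-cell markers 4 were higher in the knockout under each condition, and limma called the same number, also adjusted over the list alone. They were the MHC class II genes H2-Ab1 (log2 difference 1.72 untreated, 1.35 after R848 and 1.44 after CpG B, adjusted p = 0.0038), H2-Aa (1.88, 1.23 and 1.42, adjusted p = 0.00885), H2-Eb1 (1.62, 1.36 and 1.60, adjusted p = 0.00302) and Cd74 (1.68, 1.30 and 1.60, adjusted p = 0.0038), which macrophages also express. Of 10 markers of neutrophils and their precursors limma called 4 lower and 1 higher (6 and 3 adjusted over the list alone), including lactoferrin (Ltf, -1.19, -1.38 and -1.33) and S100a9 (-0.88 untreated and -0.79 after R848). At the 2-fold size 1 of these markers was higher and 1 lower untreated and after R848. After CpG B 1 was higher and 2 were lower. Chemokines had 3 lower and 1 higher (3 and 2 adjusted over the list alone), with Cxcl1 at -1.31 (adjusted p = 0.0038), Cxcl2 and Ccl6 lower and Ccl2 higher. The cytokine Il18 was lower (-1.58, -2.21 and -1.28, adjusted p = 0.0134) and Osm higher. In the cell-cycle list 3 genes were lower, Plk1, Mcm6 and Tyms (3 adjusted over the list alone), in the glycolysis list 2 were higher, Pkm and Vegfa, and 1 lower, Adm (the same adjusted over the list alone), and in the stress list the transcription factor Atf4 was higher (1.58, 1.47 and 1.69, adjusted p = 0.00218; 4 genes adjusted over the list alone). Single genes of other lists were called as well: Nfkbib lower among the feedback regulators (3 adjusted over the list alone), Cxcl1 and Cxcl2 again among transcripts with AU-rich elements, the arginine-synthesis gene Ass1 and the costimulatory gene Cd86 higher, and the cholesterol-synthesis gene Hmgcs1 lower. B-cell and megakaryocyte markers had 2 detected genes each, none called by limma over all genes for genotype (0 and 2 adjusted over the list alone; 1350 of 7149 genes had an unadjusted p under 0.05), and no marker of T and NK cells, erythroid cells, stromal fibroblasts or mast cells was detected.

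**Figure D2:**
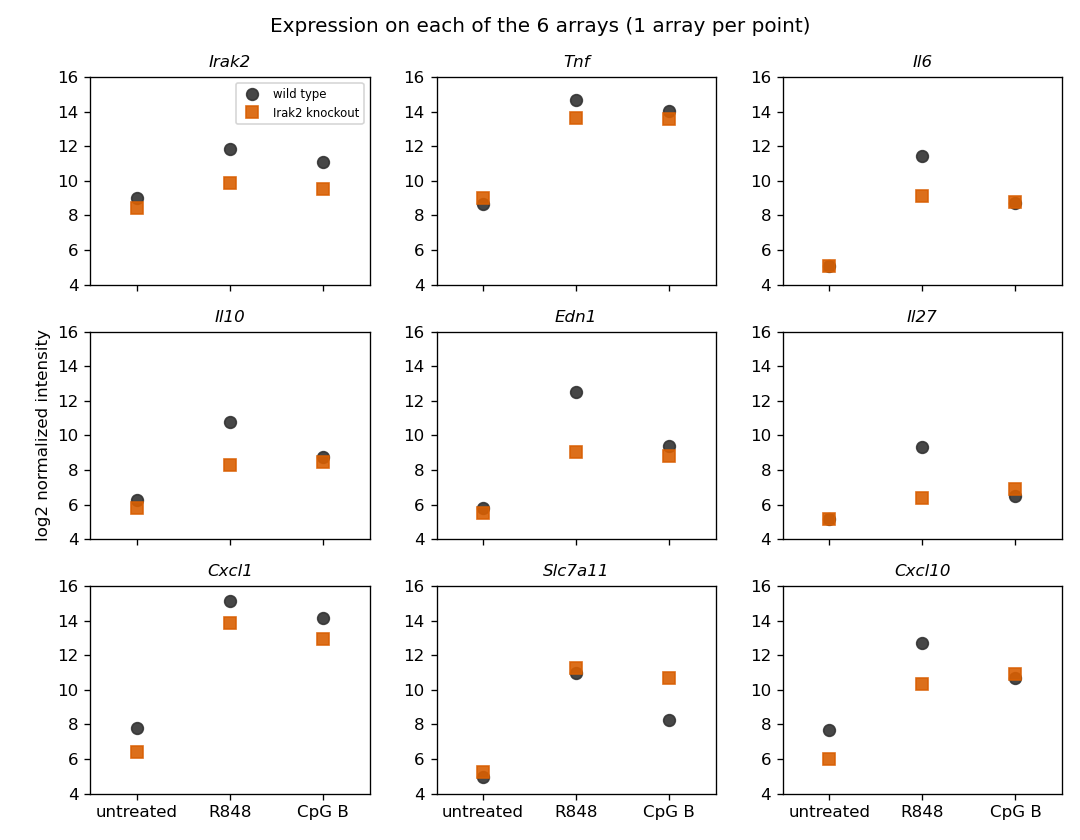
Points give log2 normalized intensity (vertical axis) for 9 genes on the 6 arrays, 1 array per point, with circles for wild type and squares for the knockout. Edn1, Il6 and Il10 were lower in the knockout after R848, by log2 differences of -3.48, -2.32 and -2.46, and Il27, below background there, by at least 6.26-fold. After CpG B the differences for Edn1, Il6, Il10 and Il27 were smaller (-0.61, 0.09, -0.30 and 0.40), and the untreated values of these 4 genes lay below background in both genotypes.

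After R848 many inducible genes were lower in the knockout than in wild type. On the stimulated arrays 311 of 6646 genes differed by 2-fold or more, 146 higher and 165 lower in the knockout. The cytokine Il19 was at least 5.86-fold lower in the knockout, the guanylate-binding protein Gbp5 at least 9.69-fold, the interleukin-27 subunit Il27 at least 6.26-fold, Edn1 11.2-fold, the chemokine-binding receptor Ccrl2 7.91-fold, metallothionein Mt2 6.73-fold and Calhm6 6.24-fold. The ERK phosphatase Dusp6 was 5.75-fold and the chemokine receptor Cxcr4 at least 3.54-fold higher. Of the lists, 10 of 14 cytokines were lower and none higher (median log2 difference -1.42), and the same held for 13 of 25 interferon-related genes (-1.08), 11 of 23 feedback regulators (-0.91), 8 of 12 secondary response genes (-1.51) and 6 of 14 chemokines (-0.39). Untreated, the median of the chemokines was already -0.82 (5 lower and 2 higher) and that of the interferon-related genes -0.28 (3 lower), so for the chemokines the median gap was not wider after R848. Gene by gene, the chemokines' R848 response in the knockout minus that in wild type had a median of -0.24, with 3 lower and 2 higher by 2-fold or more. The medians of the genotype difference after R848 each lay at percentile 0 of 10000 random lists of equal size and expression on these arrays, which describes the arrays and is not a test. MHC class II genes were higher and Ltf lower on the same pair of arrays, where 1 of 10 neutrophil markers was higher and 1 lower by 2-fold or more.

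The R848 responses of both genotypes were also compared directly. Subtracting the wild-type R848 response from that of the knockout left 232 of 6984 genes past the size, 82 higher and 150 lower. On the normalized scale, where values below background enter as they are, the most negative were Il19 (-3.81), Gbp5 (-3.30), Edn1 (-3.22), Il27 (-3.01), Calhm6 (-2.67), Ccrl2 (-2.63), the oxysterol-producing hydroxylase Ch25h (-2.45), the cytokine signalling inhibitor Cish (-2.41), Tnfaip3 (-2.37) and Il6 (-2.30). The most positive were genes that were lower after R848 in wild type, such as the cannabinoid receptor Cnr2 (2.68), Dusp6 (2.38), Angpt2 (2.10) and Tmem86a (2.05). In contrast, the chemokine Ccl3, detected on all 6 arrays, responded by more in the knockout (1.64). Among the 866 genes that rose with R848 the median response was 1.11 in wild type and 0.91 in the knockout, and 632 (73.0%) responded less in the knockout. Of the 1237 that fell, 904 (73.1%) had a smaller response in the knockout, with medians of -0.89 and -0.70. Both sets were called by the additive model, in which a response that differs between genotypes adds to the spread. They therefore lean toward genes that respond alike in both genotypes, and so do the genes called for CpG B.

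A test of this difference became possible with the recovered untreated arrays, in a limma fit of 8 arrays that was chosen after seeing the data. It assumes that stimulated arrays vary like the untreated pairs. The R848 response differed between genotypes for 11 of 7149 genes and was smaller in the knockout for all 11 in the measured values. The inhibitory Fc receptor Fcgr2b was higher after R848 by less in the knockout (difference of responses -2.14, SE 0.211, adjusted p = 0.0459), and Tmem86a, below background after R848 in wild type, was lower by less (2.06, 0.0374). Pwwp2b (2.38, 0.0374) was below background after R848 in both genotypes, so its difference was not measured above background. The other 8 genes were below background on both deposited untreated arrays, so that the spread behind their p-values was that of values near background. Of these, Edn1 (-3.02, adjusted p = 0.0298), Gbp5 (-3.28, 0.0298), Il27 (-3.34, 0.0374), the MAP kinase phosphatase Dusp2 (-2.38, 0.0374) and Mt2 (-2.14, 0.047) had some spread between untreated arrays. Il19 (-4.30), Shisa3 (-3.08) and the NADPH oxidase gene Nox1 (-2.05) had an untreated spread under 0.01, and their p-values rest on the spread of other genes alone. Adjusted over the list alone, the difference was negative (knockout minus wild type) for 9 of 14 cytokines, 9 of 23 feedback regulators (positive for 1), 8 of 12 secondary response genes, 7 of 16 transcripts with AU-rich elements, 3 of 15 effector enzymes, 4 of 16 costimulatory and adhesion molecules (positive for 1), 2 of 25 interferon-related genes and 2 of 11 NF-kB subunits and IRF factors (positive for 1). Over all genes these counts were 2, 1, 1, 0, 0, 0, 0 and 0, and 647 of the 7149 genes had an unadjusted p under 0.05. Adjusted over the list alone it was also positive for 2 of 14 chemokines (negative for 1) and negative for 1 of 28 signalling genes and 1 of 15 macrophage identity genes, against 0, 0 and 1 over all genes. Of these lists 9 cytokines, 8 feedback regulators, 9 secondary response genes and 5 chemokines were below background on at least 1 untreated array. Without any 1 of the 4 untreated arrays the count of 11 became 0, with 457 to 640 genes at an unadjusted p under 0.05, and it became 36 with an offset of 50 and 124 with an intensity trend and robust prior. Among the 6366 genes detected untreated in both genotypes, a set that leaves out genes induced from below background, it was 60 (34 positive and 26 negative), and 21 to 55 without any 1 untreated array.

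After CpG B 190 of 6967 genes differed between genotypes by 2-fold or more, 115 higher and 75 lower in the knockout. Beyond Ctse, Pclaf, Usp25 and Plk1, Slc7a11 was 5.36-fold and the glycosyltransferase Gcnt2 6.12-fold higher, and the thiopurine methyltransferase Tpmt at least 3.25-fold lower. Of the lists, 3 of 14 cytokines were higher and 1 lower (median 0.18), 3 of 12 secondary response genes were higher (median 0.55), 1 of 25 interferon-related genes was higher, Mx2 (1.40), and 2 of 23 feedback regulators were higher, Il1rn (1.85) and Cish (at least 2.10-fold). MHC class II genes were higher and Ltf and S100a9 lower on these arrays also, where 1 of 10 neutrophil markers was higher and 2 were lower by 2-fold or more. Subtracting the wild-type CpG B response from that of the knockout left 89 of 7084 genes past the size, 61 higher and 28 lower. The difference was positive for the antiviral restriction factor Bst2 (1.69), the collagenase Mmp13 (1.57) and the nucleotide kinase Cmpk2 (1.54), which were detected untreated in both genotypes. It was also positive for Slc7a11, Cxcl10, Il1a, Ccl17 and Tnfrsf1b, but these were below background on at least 1 untreated array, Il1a and Ccl17 also after CpG B in wild type, and for Slc7a11 the difference was 2.14 here and 1.05 in the submitters' processed values. Pald1 was at least 4.18-fold lower after CpG B in the knockout, where it was then below background, against a log2 difference of -0.60 in wild type, and Egr2 (-1.39), below background untreated in wild type, was higher by less. With median scaling the higher share was 84.2% and not 68.5%. Among the 336 genes that rose with CpG B the median response was 1.29 in wild type and 1.42 in the knockout, and 115 (34.2%) responded less in the knockout. The 8-array limma fit called 0 genes for this difference, with 305 at an unadjusted p under 0.05, and 6 with an intensity trend and robust prior. Adjusted over the list alone it was positive for 8 of 25 interferon-related genes, 4 of 14 chemokines, 2 of 14 cytokines (negative for 1), 2 of 12 secondary response genes and 1 of 15 effector enzymes.

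A limma interaction shared by both stimuli, planned on the 6 arrays, called 0 of 7149 genes (smallest adjusted p = 1), with 136 at an unadjusted p under 0.05. Ccl3 (1.47) and Asb2 (1.47) had the smallest p among positive values and Gramd4 (-1.69), detected only on the untreated knockout array, and Egr2 (-1.47) among negative ones. In the fixed lists it called 0 genes, and adjusted over the list alone 1, the immediate early factor Egr2, with a smaller response in the knockout.

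R848 and CpG B were further apart on the wild-type arrays than on those of the knockout. In wild type 435 of 6899 genes differed by 2-fold or more between R848 and CpG B, 252 higher and 183 lower after R848. Il1a was at least 22.9-fold higher after R848, Serpinb2 at least 16.4-fold, Cish at least 14.2-fold, complement factor B (Cfb) at least 10.3-fold and Il19 at least 7.0-fold. The interleukin-1 receptor antagonist Il1rn (3.48), Gbp5 (3.32), Mmp13 (3.14), Edn1 (3.11) and Nos2 (3.05) were higher as well, whereas Gcnt1 (-2.81), Dusp6 (-2.65) and Plau (-2.61) were lower. Of the lists, all 12 secondary response genes, 18 of 25 interferon-related genes, 12 of 23 feedback regulators and 11 of 14 cytokines were higher after R848. In the knockout 15 of 6749 genes passed the size, 10 higher and 5 lower. They were Serpinb2 (1.95), the activin subunit gene Inhba (at least 1.42-fold), Flrt3 (1.69), the histidine decarboxylase Hdc (1.62), Il1a (1.37), Il1rn (1.18), Thbs1 (1.12), Cfb (at least 2.12-fold), Cwh43 (at least 1.26-fold) and Ralgapa2 (1.07), and on the other side Plau (-1.25), Tmem53 (at least 1.11-fold lower), Gna15 (at least 1.65-fold lower), Rasgrp3 (-1.04) and Gadd45g (-1.0). With the gene required to be detected on all 6 arrays 4 genes were left, and with median scaling 76.9% and not 66.7% were higher.

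**Figure D3:**
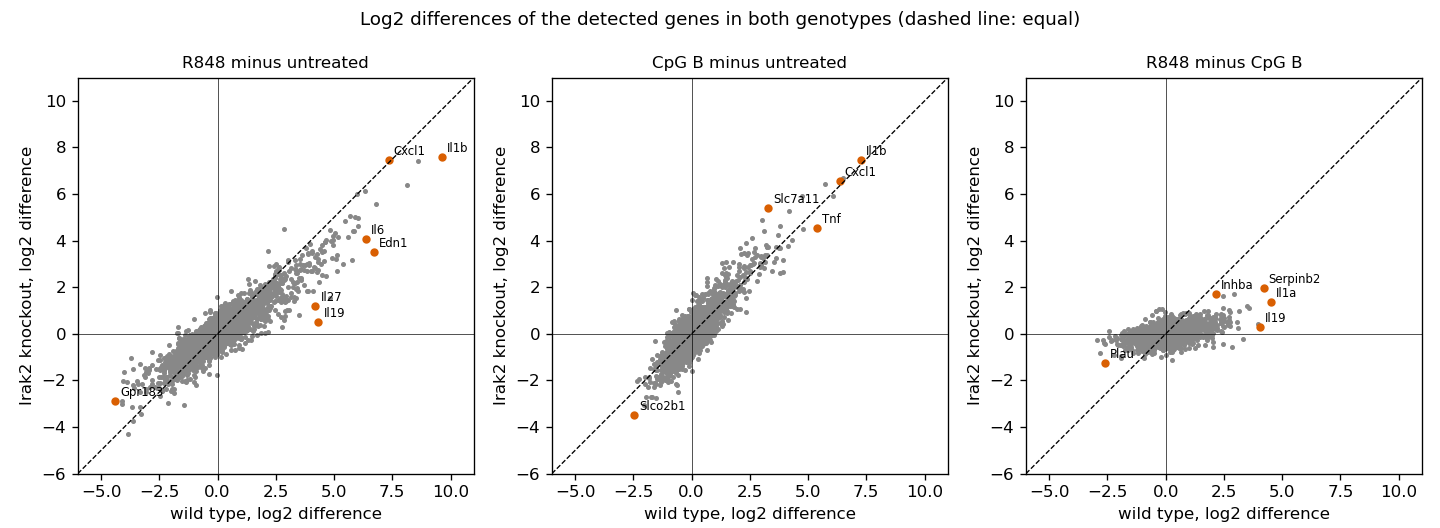
Each grey point is a detected gene, with its log2 difference in wild type on the horizontal axis and in the knockout on the vertical axis, for R848 minus untreated, CpG B minus untreated and R848 minus CpG B, and the dashed line marks equal values. The R848 minus CpG B cloud lay flat along the horizontal axis. Values below background are plotted as they are, so Il19, Serpinb2 and Il1a, below background after CpG B in wild type, have only bounds there (at least 7.0-fold, 16.4-fold and 22.9-fold higher after R848), against log2 differences of 1.95 for Serpinb2 and 1.37 for Il1a in the knockout.

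The spread of the R848 minus CpG B differences over the 7149 genes had an SD of 0.55 in wild type and 0.23 in the knockout, where the pairs of untreated arrays had 0.26 and 0.25. In the 8-array limma fit 392 genes differed between R848 and CpG B in wild type and 0 in the knockout, where 229 had an unadjusted p under 0.05. Without any 1 of the 4 untreated arrays the wild-type count was 183 to 199, and with an intensity trend and robust prior 370 genes were higher and 478 lower after R848 in wild type, and 6 genes differed in the knockout. The genotype difference itself depended on the stimulus for 26 genes, 19 of them lower and 7 higher in the knockout after R848 relative to CpG B. Among genes detected untreated, Gpr183 (2.37, adjusted p = 0.0351) and Angpt2 (2.44, 0.0351) were higher, and both were below background after R848 in wild type. Ccl5 (adjusted p = 0.0351) was the only lower gene detected untreated, and it was above background on every deposited array. It was 110-fold higher after R848 and 26.8-fold after CpG B in wild type, against 47.9-fold and 60.5-fold in the knockout. Of the 26 genes 18 were below background on an untreated array, among them Gbp5 (-3.52, 0.0304), Il1a (-3.12, 0.0351), Edn1 (-2.81, 0.0351) and Il27 (-3.40, 0.0351), which were lower. For 10 of the 18, including Il19 (-3.86), Ccl17 (-3.23), the pentraxin Ptx3 (-2.34) and Ptgs2 (-2.06), the untreated spread was under 0.01, and their p-values rest on the spread of other genes alone. Adjusted over the list alone, 10 of 14 cytokines, 15 of 25 interferon-related genes, 9 of 12 secondary response genes, 8 of 23 feedback regulators, 3 of 14 chemokines, 7 of 16 transcripts with AU-rich elements (1 higher), 4 of 15 effector enzymes (1 higher), 4 of 16 costimulatory and adhesion molecules and 1 of 15 macrophage identity genes were lower, against 3, 0, 2, 1, 2, 1, 1, 0 and 0 over all genes. The count of 26 also became 0 without any 1 of the 4 untreated arrays, with 648 to 696 genes at an unadjusted p under 0.05, 54 with an offset of 50 and 165 with an intensity trend and robust prior. Among the 6366 genes detected untreated in both genotypes, which leave out genes induced from below background, it was 56, but with the opposite balance, 18 lower and 38 higher, and it was 51 (18 lower, 33 higher) to 103 (33 lower, 70 higher) without any 1 untreated array.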

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

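Of the tests in this part, the fit of 8 arrays, the comparisons of the R848 minus CpG B differences, the slopes of the R848 and CpG B responses, the spread about the R848 slope and the test of list ratios against random lists were chosen only after the results were seen, while the comparison of the ratios of cytokines and immediate early factors was planned before.

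In the fit of 8 arrays the R848 response differed between genotypes for 11 genes, which drew attention because the difference between the groups was itself tested. By the same kind of test the genotype difference depended on the stimulus for 26 genes, after R848 relative to CpG B. An intensity trend with a robust prior gave 124 and 165 genes, and leaving out any 1 untreated array gave 0 and 0, with at least 457 and 648 genes at an unadjusted limma p under 0.05. Among the 6366 genes detected untreated in both genotypes the counts were 60 and 56 (38 of the 56 higher in the knockout, against 7 of the 26), and at least 21 and 51 without any 1 untreated array. A signal also appeared in values that the single-array comparisons did not use: if the processed untreated columns are means of 2 arrays, the sorted values of the other array lay within 0.5 units of the common quantile distribution for 99.7% of probes in wild type and 99.7% in the knockout.

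The R848 and CpG B arrays of the knockout were nearly alike (SD of the log2 difference 0.23, 23 genes past 2-fold among 7149). If both had carried the same RNA, their difference would be unrelated to that of wild type. Over the 435 genes past 2-fold in wild type the correlation across genes was r = 0.676 (Spearman rho 0.665; r = 0.673 without the 2 farthest genes), above the highest r of 0.285 from sign-flipped sets, though genes are not independent replicates. Exchanged labels of the 2 arrays would turn the signs, and 80.2% of these genes had the same sign. A knockout difference that keeps the direction of wild type at a slope of 0.180 leaves partial mixing of the samples and an effect of the genotype open, and neither was tested.

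The R848 response was smaller in the knockout for 73.0% of the genes that rose. A compression of every knockout array would give gene groups like ratios of knockout to wild-type response, and the medians of 8 immediate early factors (0.688) and 13 cytokines (0.758) differed by -0.071, within the SD of 0.141 of random lists. It would also lower the CpG B response, but over the 2103 genes called for R848 the slope of the knockout's CpG B response on that of wild type was 1.11 (SD 0.014 over resampled genes), against 0.757 for R848. Genes are not independent replicates, so this SD leaves out variation between arrays or cultures. Both knockout responses also share 1 untreated array. A single scaling of the R848 response and differences between genes cannot be told apart: of 13 lists none departed from random lists of like wild-type response in its median ratio (smallest adjusted permutation p = 0.133, cell cycle, 0.962 against 0.681), a departure of 0.281 that also keeps the lists from being called alike, and the SD about a single slope was 1.17, 1.67 or 1.35 times that of the untreated pairs for genes chosen by the additive fit, by size in wild type alone or by the 8-array response of wild type, which decides nothing while those pairs may be technical repeats. A weaker R848 stimulus in that culture, a compression of the R848 array alone, partial mixing of the 2 stimulated knockout samples and an effect of the genotype stay open, untested.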

How the results depend on the processing

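Under the settings chosen beforehand no named gene past 2-fold changed sign. For some settings this was fixed in advance. The genes named for the largest differences had to have the same sign in the processed values, and a detection filter leaves the value of a gene unchanged. The median over all tested genes, near 0 in every comparison, did change sign in some with median scaling, as for R848 in wild type (-0.10 to 0.003). Of 544 list medians under alternatives 488 moved by less than the spread between untreated arrays (SD 0.26 log2), 56 by more, and 0 of those of at least 1 in size reversed. Counts are given in the order R848 and CpG B in wild type, R848 and CpG B in the knockout, genotype untreated, after R848 and after CpG B, difference of R848 and of CpG B responses, and R848 against CpG B in wild type and knockout. A size of 1.5 left 557, 179, 341, 262, 62, 107, 75, 71, 15, 181 and 4 genes, as a stricter size must. Detection on all 6 arrays left 682, 205, 433, 316, 76, 161, 96, 107, 35, 231 and 4, since it removes genes that are dim in 1 condition. An offset of 50 gave 53 genes for the difference of CpG B responses and 7 for R848 against CpG B in the knockout, as a larger offset shrinks dim differences. In limma, leaving out the genotype term gave 1280 (R848) and 259 (CpG B). The genotype effect gave 378 with an intensity trend and robust prior, 76 without the agent term, 9 without both untreated arrays, 90 without both CpG B arrays and 140 without a detection filter, and CpG B gave 251 without that filter. For these the cause was not tested, apart from fewer arrays in the fits without an agent. All other counts under the settings chosen beforehand stayed within 1.5 times. In the fit of 8 arrays, chosen after seeing the data, R848 against CpG B in wild type went from 392 to 183 to 199 without any 1 untreated array, to 370 higher and 478 lower with an intensity trend and robust prior and to 610 among genes detected untreated in both genotypes. The trend also gave 6 genes in place of 0 for R848 against CpG B in the knockout and for the difference of CpG B responses. No paired analysis was possible because each group has 1 array and the labels carry no replicate numbers. Signal over background limits the dim genes: 34.9% to 37.8% of probes were detected per array, and folds against undetected genes are bounds.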

Other observations

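Of the tests in this part, the probe comparison and the test over chromosomes were chosen only after the result was seen, while the tests of chromosome 6, of neighbouring genes and of other splits were planned before their results were known.

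Genes outside the fixed lists were called by limma as well. The DNA mismatch repair gene Msh6 (-2.79, limma adjusted p = 0.00203) and Otulinl (-1.85, 0.00203) fell, as did Rcbtb2 (-1.64, 0.00172), and with CpG B the cell-cycle regulator Rgcc (-1.47, 0.00616) and the thioesterase Acot1 (-1.62, 0.0067) fell. Genes that rose with R848 included the cytoskeletal regulator Cdc42ep2 (4.59, 0.000938) and the repressor Zhx2 (2.71, 0.000938), and Marcksl1 rose with CpG B (2.73, 0.00185). Genotype was accompanied by higher B3galt6 (2.45, 0.00084), Fgfr1op2 (2.43, 0.00084), the DNA damage kinase Atm (2.17, 0.000935) and the mitochondrial import gene Tomm22 (2.03, 0.000991), and by lower Trappc12 (-2.26, 0.000935), Gnb4 (-1.80, 0.00136) and the collagen gene Col4a5 (-1.69, 0.00163). For Fgfr1op2 the other detected probe had a mean log2 difference of 0.11, so the difference rests on a single probe. For Atm and Gnb4 the other probe differed the same way (1.37 and -0.66).

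A set of 63 genes differed between genotypes by 2-fold or more in all 3 conditions. DNA of the 129 strain carried along beside Irak2 would place them on chromosome 6, and 3 of them (4.76%, against 4.93% of tested genes) lay there (one-sided Fisher's exact p = 0.607). The test covers the whole chromosome, so it cannot exclude a short segment beside Irak2, and distances to Irak2 were not examined. Segments of strain DNA elsewhere may account for part of the set: 8 pairs lay within 5 places of each other in gene order, against a median of 3 in 10000 random sets (one-sided permutation p = 0.0034), though 2 of the pairs are MHC class II genes, which are regulated together. Strain variants under single probes may contribute as well. Other probes of the same gene agreed for 7 of 10 genes (70%), with Taf6, Fgfr1op2 and Atp2c1 the exceptions. They agreed for 143 of 146 genes (97.9%) past 2-fold after R848 in both genotypes (one-sided Fisher's exact p = 0.00348). Agreement needed the same sign and a minimum size. Sizes were not matched between the gene sets, so larger differences could agree more easily. Of the 10 splits of the arrays into 3 and 3, which are too few for a share under 0.05, 1, the real one, reached its 243 called genes and the highest other gave 1. In the other splits any genotype difference adds to the residual spread, which lowers their counts, so this contrast decides nothing. An effect of Irak2 loss itself stays open, untested.

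Chromosome 9 held 14 of the 63 genes (22.2%, against 5.68% of tested genes; one-sided Fisher's exact p = 8.44e-06, adjusted p = 0.000177 over 21 chromosomes), among them Atp2c1, Dusp7, Parp3 and Hemk1, which lie near each other in gene order. Ltf, Il18, Pclaf, Lars2 and Atm, named above for their difference between genotypes, were also among the 14. Tomm22 and Apobec3 on chromosome 15, Uchl1 and Atp10d on chromosome 5, and Fundc2 and Pls3 on the X chromosome were further neighbouring pairs.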
